A study of Mus musculus with 3 samples.

How the data were processed

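Nucleosomal DNA was profiled in 1 library each of wild-type, Snf5-deficient and Brg1-deficient primary mouse embryonic fibroblasts. Per the labels' protocols, cells were infected with a Cre retrovirus and selected in puromycin, nuclei were treated with micrococcal nuclease, and gel-extracted fragments were prepared for Helicos sequencing. Genotypes were taken from the labels. The deposited values are counts of reads per chromosome, strand and position, with no normalization seen in them. Per the submitters' processing notes the genome build was mm9. The aligner, its filters and the step that limits reads per position are not given in the sources used here. No count exceeded 2 on any chromosome other than Y, where the largest was 4. Such a limit removes reads where reads are dense, and more of them in deeper libraries. The base from which positions are counted, and which end of a read they mark, are not stated either. Positions are printed as the files give them.

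Depth was 79042917 reads for wild type, 66179330 for Snf5 and 37031105 for Brg1, so values of the Brg1-deficient library carry the widest counting error. Positions with 2 or more reads were 2.89%, 2.20% and 1.37% of those seen. Ratios were scaled to autosomal reads. Intervals of ratios are exact conditional (Clopper-Pearson) intervals at 95%, and they cover counting error only. Intervals of distances come from 200 resamples of the 1-Mb windows, and from 100 resamples for the classes of windows. With 1 library per genotype no test between genotypes was possible and no p-value is given.

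Fragment length was the most frequent distance, between 100 and 220 bp, from read positions of the plus strand to those of the minus strand. This takes a position as the start of the read. Were it the leftmost base, fragment lengths would be too short by the read length, and read centres of the minus strand would be misplaced by it. The nucleosome repeat length was the slope of peak position on peak number for peaks 1 to 5 of the distances between read positions on the same strand, smoothed with an SD of 15 bp. Windows of 10 kb entered with 100 or more reads over the 3 libraries, and log2 ratios had a pseudocount of 0.5 reads. Positioned nucleosomes were the 50000 windows of 30 bp per library with the most read centres, at least 500 bp apart, after read positions were shifted by 73 bp. Ties were broken at random with a fixed seed. Depleted sites had at most 1 read centre in the core and a minimum number of read centres on both sides, from 100 to 260 bp away. That minimum was 16 for wild type, 14 for Snf5 and 8 for Brg1, and 20, 18 and 11 in the stricter set, both chosen after the data were seen.

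Missing segments were runs of 2 or more 1-kb windows holding at most 0.2 of the expected reads. The expectation came from the other libraries and the surrounding windows, had to reach 8 reads, and each other library had to exceed 0.5 of their pooled density. This definition and threshold were chosen after reads around recalled mm9 positions of the targeted genes had been seen, and after a first definition with a threshold of 0.1 had not listed the chromosome 10 segment. The named windows were the 5 highest and 5 lowest 10-kb ratios per mutant, outside 1-Mb windows whose own ratio was off by more than 1.2-fold, a rule fixed before the data were examined.

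Promoter profiles, promoter ratios, gene lists and promoter classes had been planned, together with their alternatives, and were not run. The gene table used here is of assembly GRCm38, a different build, so it served only for names and chromosomes of 2 genes, Smarcb1 and Smarca4, and no list of genes has a result. The windows, positioned sites and scan fixed beforehand as the fallback took their place, and the change shared by the mutants was computed over windows in place of genes. No genome sequence was used, so base composition was not examined.

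Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The steps were tested on simulated data. Simulated arrays gave repeat lengths within 0.2 bp and fragment lengths within 2 bp of the truth. Of 50 missing segments placed in each simulated library, 46, 46 and 42 were found at the wild-type, Snf5 and Brg1 depths, with 0 others. They were placed only in 1-kb windows with at least 15 expected reads, and kept about 0.1 of their reads. Recovery was thus not measured for sparser windows, which the search admits from 8 expected reads. Nor was it measured for a weaker loss, such as the ratio of 0.169 of the chromosome 10 segment. For 10-kb windows raised 1.5-fold, the median log2 ratio was 0.59 at the Snf5 depth and 0.61 at the Brg1 depth. Alternatives included counting each position once, equal depth, other window sizes, other peaks, opposite-strand distances, fewer sites, other shifts and a split of the wild-type reads.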

Results

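Nucleosomal DNA was sequenced from primary mouse embryonic fibroblasts of 3 genotypes, wild type, Snf5-deficient and Brg1-deficient. The cells came from embryos at day 13.5 and received Cre recombinase by retrovirus, per the labels' protocols. Snf5 (Smarcb1) is a core subunit of the Swi/Snf chromatin-remodelling complex and a tumour suppressor. Brg1 (Smarca4) is an ATPase of the same complex. Micrococcal nuclease cuts DNA between nucleosomes, so read density reports where nucleosome-sized DNA was recovered. The series title names the question of how Swi/Snf sets nucleosome occupancy at target promoters. No promoter positions of the genome build of the files were used here, so the comparisons below are of spacing, positioned nucleosomes and regions of the genome. Each genotype had 1 library, which leaves no replicate check for any difference and no test between genotypes. The intervals given cover counting error or resampling of genome windows within these libraries only.

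The wild-type library held 79042917 reads, the Snf5-deficient library 66179330 and the Brg1-deficient library 37031105. On the 19 autosomes this came to 30.6, 25.6 and 14.3 reads per kb. A 10-kb window therefore held many reads in each library, whereas a single nucleosome held few. No autosomal position and strand carried more than 2 reads in any library. Reads placed at random at the same depth would have put 3 or more on 2907 positions of the wild-type library, 1705 of the Snf5-deficient library and 298 of the Brg1-deficient library.

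Reads were first searched for deletions at the targeted genes. A segment of chromosome 10 from 75383000 to 75384999 (build mm9) was nearly without reads in the Snf5-deficient library. It held 92 reads in the wild-type, 13 in the Snf5-deficient and 37 in the Brg1-deficient library. Scaled to autosomal reads, the Snf5-deficient over wild-type ratio was 0.169 (95% interval 0.0867 to 0.303), and the Brg1-deficient over wild-type ratio was 0.861 (0.571 to 1.27). Relative to the 10 kb on either side, the density was 0.898 (0.718 to 1.11) in wild type, 0.180 (0.0953 to 0.309) in the Snf5-deficient library and 1.57 (1.08 to 2.23) in the Brg1-deficient library. The last value rests on flanks with few Brg1-deficient reads for the depth of the library, 235 against 1024 in wild type. Part of those flanks, from 75389000 to 75390999, was itself a Brg1-deficient missing segment at a threshold of 0.25. The bounds are those of the 1-kb windows of the search, and the next 500 bp, to 75385499, were low as well, with 5 Snf5-deficient reads against 28 in wild type. Smarcb1 lies on chromosome 10, but the annotation used here was of another build, so whether the segment is within the gene was not determined.

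**Figure D1:**
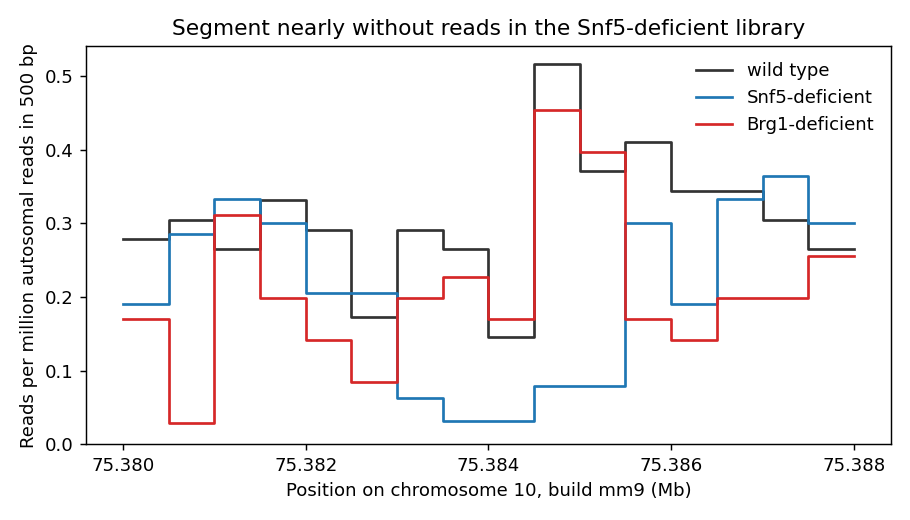
Reads in 500-bp windows, scaled to the autosomal reads of each library (vertical axis), against position on chromosome 10 in build mm9 (horizontal axis), 1 line per library. The Snf5-deficient line is low between 75383000 and 75384999, where the library held 13 reads against 92 in wild type, and in the next window to 75385499, with 5 reads against 28.

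The search that listed this segment was not blind. Reads around approximate mm9 positions of Smarcb1 and Smarca4, recalled from general knowledge and not taken from an annotation, were looked at before the search was defined. The definition and its threshold of 0.2 of the expected reads were chosen after the values were seen. Under that definition the Snf5-deficient library had 1 missing segment, the wild-type library 5 and the Brg1-deficient library 54. A first definition used 2-kb sums, a threshold of 0.1, at least 15 expected reads and no correction for the surroundings. It gave 12 segments for Snf5, 30 for wild type and 93 for Brg1, and it did not list the chromosome 10 segment, whose ratio to wild type of 0.169 lies above that threshold. At 0.2 it gave 38, 197 and 635, and the segment was 1 of the 38. Under the chosen definition, a threshold of 0.1 left 0 segments in the Snf5-deficient library. For Brg1, 4 of the 54 segments lay on chromosome 9, which carries Smarca4, and none stood out as the targeted one. The label of the Brg1-deficient library thus has no check from its own reads.

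Nucleosomes were more closely spaced in both mutant libraries than in the wild-type library. Repeat length here is the spacing of peaks 1 to 5 of the same-strand distances, which need not equal the mean distance between neighbouring nucleosomes. It was 191.4 bp (95% interval 190.8 to 192.2) in wild type. It was 187.9 bp (187.6 to 188.2) in the Snf5-deficient library and 189.3 bp (188.9 to 189.8) in the Brg1-deficient library. The difference from wild type was -3.5 bp (-4.2 to -2.9) for Snf5 and -2.1 bp (-3.0 to -1.3) for Brg1. The Snf5-deficient value was the shorter one on 19 of 19 autosomes, and the Brg1-deficient value on 18 of 19. Between the mutants, the Brg1-deficient repeat length was longer by 1.4 bp (0.8 to 2.0). For scale, values of single autosomes varied with an SD of 1.31 bp in wild type, 0.808 bp in the Snf5-deficient and 1.18 bp in the Brg1-deficient library.

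**Figure D2:**
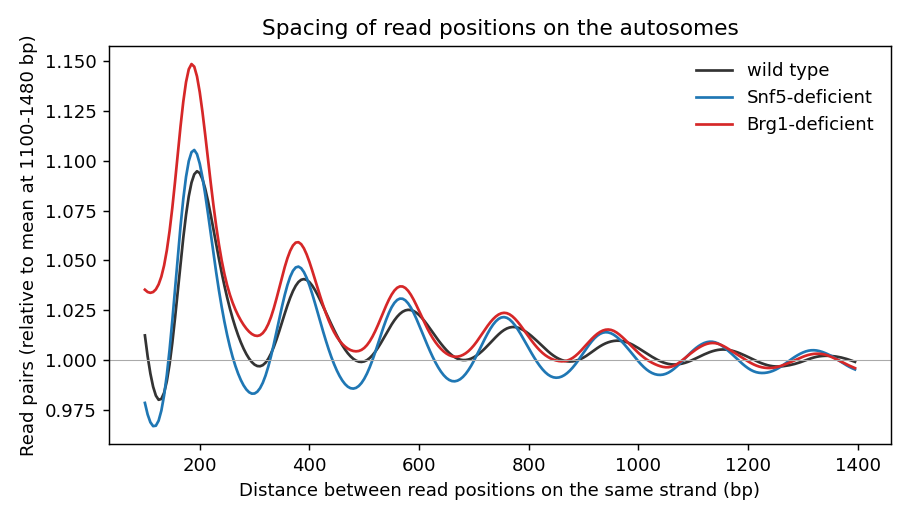
Number of read pairs at each distance between read positions on the same strand, relative to the mean beyond 1100 bp (vertical axis), against that distance in bp (horizontal axis), 1 line per library. The fifth peak stands at 962 bp in wild type, 941 bp in the Snf5-deficient and 944 bp in the Brg1-deficient library.

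The peaks of the mutant libraries moved away from those of wild type with distance, whereas the mutants stayed within 3 bp of each other. The first peak stood at 196 bp in wild type, 189 bp in the Snf5-deficient and 186 bp in the Brg1-deficient library. By the fifth peak the positions were 962, 941 and 944 bp. The first peak was 1.098 times the following trough in wild type (1.097 to 1.099), 1.124 in the Snf5-deficient (1.123 to 1.126) and 1.135 in the Brg1-deficient library (1.133 to 1.136). The libraries also differed in the distance between read positions of opposite strands, taken here as fragment length. It was 164 bp in wild type, 158 bp in the Snf5-deficient and 168 bp in the Brg1-deficient library. Single autosomes gave 163 to 165, 158 to 159 and 167 to 170 bp. These are fragment lengths only if a position marks the start of the read, which is not stated. If it marks the leftmost base, they are too short by the read length. A wave with a period near 10.1 bp, the helical turn of DNA on the nucleosome, had an amplitude of 0.243% in wild type, 0.176% in the Snf5-deficient and 0.445% in the Brg1-deficient library.

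Repeat length was longer in read-dense than in read-poor regions in the wild-type library, and by less in the Brg1-deficient library. The same contrast was not detectable in the Snf5-deficient library. This split of the genome was added after the data were seen. The 2380 windows of 1 Mb with enough reads were ranked by mean read density over the 3 libraries and cut into 4 classes of 595. The classes therefore do not follow the density of each library by itself. Log2 density of the Brg1-deficient library had a correlation of only 0.296 with wild type over these windows. From the least dense to the densest class the wild-type repeat length was 188.0, 189.5, 190.7 and 193.0 bp. The Snf5-deficient values were 187.8, 187.1, 188.2 and 188.2 bp, and the Brg1-deficient values 188.8, 188.9, 189.7 and 190.5 bp. The densest minus the least dense class was 5.0 bp (3.3 to 6.8) in wild type, 0.4 bp (-0.5 to 1.3) in the Snf5-deficient and 1.7 bp (0.55 to 3.2) in the Brg1-deficient library. The Snf5-deficient classes were not all alike, since the second class, at 187.1 bp (186.4 to 187.7), lay below the densest, at 188.2 bp (187.8 to 188.8). In the least dense class the intervals of the 3 libraries overlapped, and the Brg1-deficient value of 188.8 bp was above the wild-type value of 188.0 bp. The intervals of wild type and the Brg1-deficient library overlapped in every class but the densest.

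**Figure D3:**
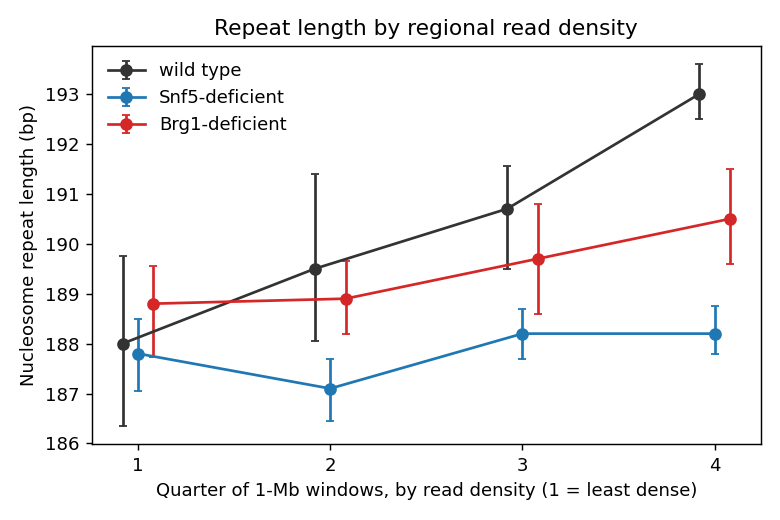
Nucleosome repeat length in bp (vertical axis, not from 0) in 4 classes of 595 windows of 1 Mb ordered by read density (horizontal axis), with 95% intervals from resampling windows. Wild type goes from 188.0 to 193.0 bp, while the Snf5-deficient library stays between 187.1 and 188.2 bp.

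Positioned nucleosomes of the wild-type library were less prominent in the Brg1-deficient than in the Snf5-deficient library. At the 50000 autosomal sites where wild-type read centres were most concentrated, read centres of the Snf5-deficient library stood at 4.80 times their level at 600 to 1000 bp. Those of the Brg1-deficient library stood at 3.37 times, a ratio of 0.702 (0.696 to 0.708). At sites taken from the Snf5-deficient library, the wild-type height was 4.84 and the Brg1-deficient height 3.83, a ratio of 0.791 (0.785 to 0.797). At sites taken from the Brg1-deficient library, the Snf5-deficient height of 3.796 was 1.11 times (1.104 to 1.12) the wild-type height of 3.41. At 120 bp from these sites, towards higher positions, read centres stood at 1.45 in wild type and 1.59 in the Snf5-deficient library. At 190 bp they stood lower, at 1.24 and 1.30. A distance of 120 bp is shorter than the repeat length, so not all of these sites need be positioned nucleosomes. Neighbouring nucleosomes were not lower in the Brg1-deficient library. At wild-type sites they stood at 1.37 times the outer level in the Snf5-deficient and 1.39 times in the Brg1-deficient library. At Snf5-deficient sites they stood at 1.33 times in wild type and 1.39 times in the Brg1-deficient library, the opposite direction to the centre. The sites were never taken from a library under comparison. All read positions were shifted by 73 bp, although fragment length differed between libraries. With shifts set from each library's own fragment length, the ratios at wild-type, Snf5-deficient and Brg1-deficient sites were 0.752, 0.807 and 1.07. Their directions held, but their sizes moved beyond the counting intervals.

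**Figure D4:**
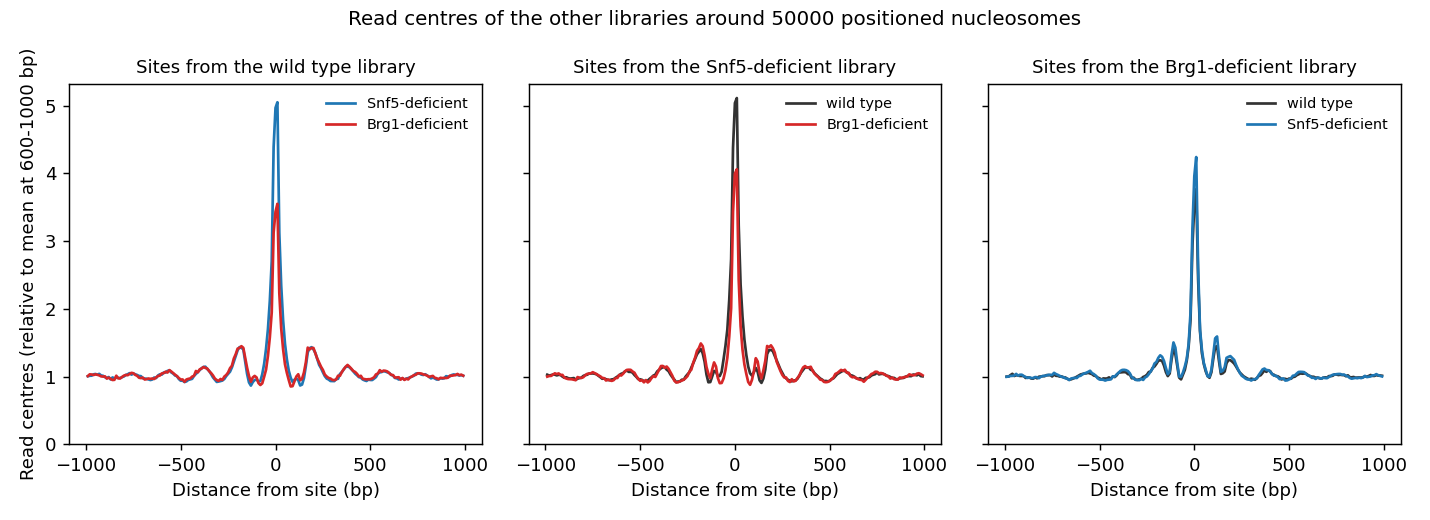
Read centres relative to their mean at 600 to 1000 bp (vertical axis) against distance from the site in bp (horizontal axis), for sites from each library in turn (panels) and reads of the other libraries (lines). The centre at wild-type sites averages 4.80 in the Snf5-deficient and 3.37 in the Brg1-deficient library.

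Sites that lacked nucleosome reads between dense neighbours in the wild-type library also had a low read density in the Snf5-deficient library, whereas the Brg1-deficient density there was close to that of the surroundings. This comparison was added after the data were seen. At 5031 such sites, the core density was 0.653 of the surroundings in the Snf5-deficient and 0.977 in the Brg1-deficient library, a ratio of 1.499 (1.46 to 1.54). At 1995 sites defined in the Snf5-deficient library, the core density was 0.673 in wild type and 0.987 in the Brg1-deficient library. The dense neighbours were also nearer the surroundings in the Brg1-deficient library. They stood at 1.42 against 1.86 in the Snf5-deficient library at wild-type sites, and at 1.61 against 2.04 in wild type at Snf5-deficient sites. The Brg1-deficient profile was thus flatter in core and neighbours alike. With a stricter demand on the neighbours, the ratio was 1.46 (1.34 to 1.60) at 384 wild-type sites. At 68 Snf5-deficient sites it was 1.099 (0.876 to 1.37), so a difference was not detectable there. The core density at these sites was 0.664 of the surroundings in wild type and 0.730 in the Brg1-deficient library, low in both. At 8256 sites defined in the Brg1-deficient library, the core density was 0.952 in wild type and 0.979 in the Snf5-deficient library, a ratio of 1.03 (1.01 to 1.04). At 128 such sites under the stricter demand it was 0.846 and 0.785, a ratio of 0.926 (0.826 to 1.04), so the direction turned. The shallower Brg1-deficient library needed a lower read minimum, and chance gaps enter its list more easily.

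The Brg1-deficient library had fewer reads than wild type in regions dense in the wild-type or Snf5-deficient library, and more in regions poor there. The Brg1 ratio was not ranked in the Brg1-deficient library. Among the 238 densest windows of 1 Mb, ranked in the Snf5-deficient library, the Brg1-deficient over wild-type log2 ratio was -0.53, with 237 of 238 windows below 0. Among the 238 least dense it was 0.30, and in the next 238 it was 0.40. Ranked in the wild-type library, the log2 ratio for Brg1 was 0.34 in the least dense class, 0.44 in the next and -0.56 in the densest. For Snf5 it ran from 0.12 to -0.12. Ranking in the wild-type library itself favours this order through counting noise, which is small at this depth. It also favours it through any other feature of that library alone, the size of which was not measured. Ranked in the Brg1-deficient library, whose densities differ, the Snf5 ratio ran the other way, from -0.05 to 0.08. Counting error moved these ratios only in the third decimal. Log2 densities of 1-Mb windows had a correlation across windows of 0.983 between wild type and the Snf5-deficient library. It was 0.296 between wild type and the Brg1-deficient library and 0.432 between the mutants, and windows are not independent replicates.

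**Figure D5:**
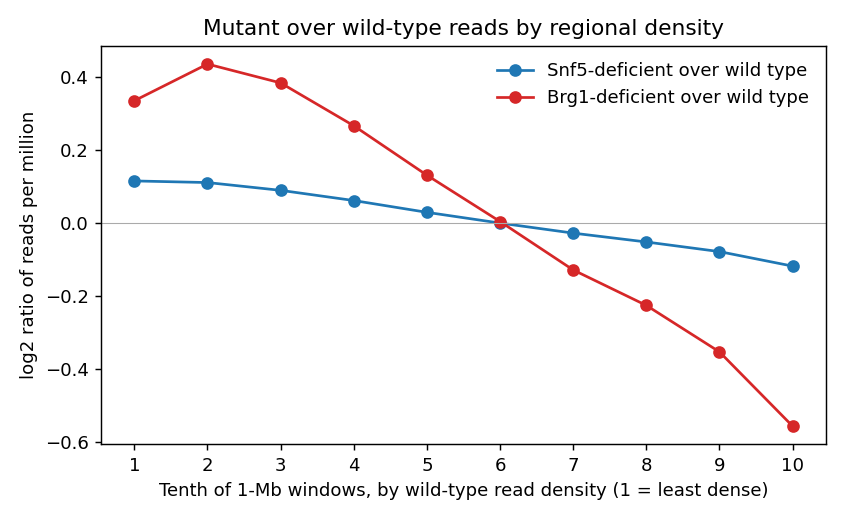
Log2 ratio of scaled reads, mutant over wild type (vertical axis), in 10 classes of 238 windows of 1 Mb ordered by wild-type read density (horizontal axis). The Brg1-deficient line starts at 0.34, is highest at 0.44 in the second class and ends at -0.56, and the Snf5-deficient line runs from 0.12 to -0.12.

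Ratios also differed between whole chromosomes. The Brg1-deficient over wild-type ratio was lowest on chromosome 7, at 0.864 (0.862 to 0.865), and chromosome 11, at 0.897 (0.895 to 0.898). The wild-type density of chromosome 7 was 0.994 of the autosomal mean and that of chromosome 11 was 1.14. It was highest on chromosome 3, at 1.113 (1.111 to 1.115), and chromosome 16, at 1.08 (1.07 to 1.08). The Snf5-deficient ratios stayed closer to 1, with 0.970 on chromosome 7 and 0.972 on chromosome 11. Within each of the 19 autosomes, the windows denser in the Snf5-deficient library had the lower Brg1 ratio, by -0.40 to -0.65 on the log2 scale. The windows denser in the Brg1-deficient library had the higher Snf5 ratio on all 19, by 0.03 to 0.12, a sign that depends on the ranking library as above. Single regions were chosen after their values were seen. The Brg1-deficient library was lowest at 152000000 to 152999999 on chromosome 7, with a ratio of 0.538 (0.524 to 0.552) against 0.922 for Snf5. It was highest at 40000000 to 40999999 on chromosome 17, with 1.58 (1.54 to 1.62) against 1.18 for Snf5. Windows dense within their own surroundings differed too. In 6530 windows of 1 kb that stood 6 SD or more above their surroundings in the Snf5-deficient library, wild-type reads were 2.18 times and Brg1-deficient reads 1.93 times their own surroundings, a log2 difference of -0.17. In 130030 windows 3 SD or more below their surroundings the log2 difference between Brg1-deficient and wild-type reads was -0.01. In 171876 windows equally far below their surroundings in the wild-type library, Brg1-deficient reads were 0.378 and Snf5-deficient reads 0.348 of their surroundings, a log2 difference of 0.12.

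Windows of 10 kb showed a small spread for Snf5 and a large one for Brg1. Of 235739 windows with 100 or more reads, 582 were at least 1.5-fold higher and 102 at least 1.5-fold lower in the Snf5-deficient library. Simulated unchanged libraries of these depths, which differed by counting noise only, gave 31 and 47. In the Brg1-deficient library 24548 windows (10.4%) were higher and 25046 (10.6%) lower, against 117 and 162 in the simulation. This near balance was particular to 10-kb windows. In windows of 50 kb, 1990 were higher and 4129 lower, and in windows of 1 Mb, 2 were higher and 111 lower. The regional differences of the Brg1-deficient library described above enter these counts and are not in the simulation. The counts are therefore not numbers of separately changed windows. The SD of the log2 ratio was 0.17 for Snf5 (simulated 0.13) and 0.45 for Brg1 (simulated 0.15). The log2 ratios of both mutants had a correlation across windows of 0.626, where simulated unchanged libraries sharing the wild-type reads gave 0.380. The covariance was 0.0494 against a simulated 0.00714. With the wild-type reads split at random, a part for each mutant, the correlation was 0.471 and the covariance 0.0421. Both parts came from the same wild-type library. The split thus removes shared counting noise, but not other features of that library that enter both ratios. In windows of 1 Mb the correlation was higher, at 0.873, against 0.355 simulated and 0.863 with the split. There 91.4% of windows had ratios of the same sign in both mutants. At that scale too, a change common to the mutants cannot be told apart from a feature of the wild-type library.

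The windows with the lowest Snf5 ratios formed a single stretch. All 5 lay between 77720000 and 77779999 on chromosome 2, with ratios of 0.374 to 0.392. The Brg1 ratios there were 0.356 to 0.560, so the wild-type library was the one that stood apart. The highest Snf5 ratio was 4.71 (3.46 to 6.52), at 67590000 to 67599999 on chromosome 6, where the Brg1 ratio was 5.85 (4.23 to 8.19). The next was 4.05 (2.69 to 6.26) at 111430000 to 111439999 on chromosome 7, where the Brg1 ratio was 3.66 (2.31 to 5.90). The 1.2-fold rule on 1-Mb windows left 105645 of the 235739 windows for the Brg1 ranking, against 234861 for Snf5. Of the 5 windows with the lowest Brg1 ratios among those left, 4 lay between 61810000 and 61949999 on chromosome 13. Their Brg1 ratios were 0.117 to 0.154 and their Snf5 ratios 0.829 to 1.01. The remaining one, at 27730000 to 27739999 on chromosome 7, had a Brg1 ratio of 0.137 (0.0489 to 0.309). Windows such as these hold few reads or differ as blocks, and copy-number differences between the embryos were not tested.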

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

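Chromosome Y was left out of the comparisons in the results and still held reads in each library, which is what singled it out. There were 21977 reads in wild type, 21875 in the Snf5-deficient and 12294 in the Brg1-deficient library, far above the 3 reads that a count of 0 allows. Scaled to autosomal reads, the ratio to wild type was 1.19 (1.17 to 1.21) for Snf5 and 1.198 (1.17 to 1.22) for Brg1. No biological explanation was tested.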

How the results depend on the processing

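Of 90 alternatives for 36 values, 62 stayed within tolerance of the main value, 27 moved and 1 turned direction. The tolerance was the error or spread for a value and a factor of 1.5 for a count. A shift of 82 bp, equal depth and a level correction for distances, and missing-segment settings were chosen after seeing the data. So were density classes, depleted sites and shifts set from each library's own fragment length. These own shifts were 82 bp for wild type, 79 bp for Snf5 and 84 bp for Brg1. The cause was not tested for any move below. Each position counted once: densest 1-Mb windows, log2 0.078 for Snf5 ranked in the Brg1 library (-0.11 ranked in wild type) and -0.52 for Brg1 ranked in the Snf5 library, and correlation of the mutants 0.622. The split of wild-type reads gave 0.471. Windows of 50 kb: 0.157% higher and 0.0189% lower for Snf5, 4.17% and 8.66% for Brg1. Missing segments at thresholds of 0.1 and 0.25: 0 and 2 for Snf5, 11 and 125 for Brg1. With uncorrected 2-kb sums and at least 15 expected reads, at 0.1 and 0.2: 12 and 38 for Snf5, 93 and 635 for Brg1. The count of 1 for Snf5 thus depends on the definition. Height at wild-type sites, Brg1 over Snf5: 0.695 at equal depth, 0.740 with 82 bp, 0.752 with own shifts. At Snf5 sites, Brg1 over wild type: 0.820 with 10000 sites, 0.772 at equal depth, 0.820 with 82 bp, 0.807 with own shifts. At Brg1 sites, Snf5 over wild type: 1.14 with 10000 sites, 1.104 with 82 bp, 1.07 with own shifts. Cores of depleted sites under the stricter demand: 1.099 at Snf5 sites, and 0.926 (0.826 to 1.04) at Brg1 sites, where 1.03 (1.01 to 1.04) turned direction. Promoter settings were not run. No paired analysis was possible because each genotype had 1 library, and no replicate could be left out. The Brg1 library, with 14.3 autosomal reads per kb, had the fewest reads behind each site.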

Other observations

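The tests on digestion and on the chromosome 10 segment were chosen after the results were seen, as was the split by read density itself.

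Chromosome X carried 0.681 of the autosomal density in wild type, 0.694 in the Snf5-deficient and 0.725 in the Brg1-deficient library. Pairs of reads with the minus-strand position 6 to 10 bp before the plus-strand position were 1.36 times the distant level in the Brg1-deficient library, against 1.17 in wild type and 1.16 in the Snf5-deficient library.

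The Brg1-deficient library had fewer reads in regions that were dense in the wild-type or Snf5-deficient library. Repeat reads left in the deposited counts were not the cause, since the log2 ratio in the densest 238 windows was -0.52 with each position counted once. At most 2.89% of positions held 2 or more reads, so this count could move the ratio only little. Repeat reads removed before deposit were not tested. Copy number of single chromosomes would not place the lower ratio in the denser windows of 19 of 19 autosomes, ranked in the Snf5-deficient library. A difference in digestion that goes with fragment length cannot be told apart from genotype. With a shorter opposite-strand distance than wild type, the Snf5-deficient library had a log2 ratio in the densest windows of -0.12 when ranked in wild type and 0.08 when ranked in the Brg1-deficient library. Base composition, preparation and loss of Brg1 also stay open, with 1 library per genotype and no genome sequence.

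The wild-type repeat length was longer in read-dense regions, with little of this in the Snf5-deficient library. A falling baseline of the distance profile was tested by dividing it by its surroundings, which left a difference of 5.0 bp. Equal depth left 5.7 bp, and classes drawn from the Snf5-deficient library left 4.6 bp. The difference in the Brg1-deficient library was 1.7 bp (0.55 to 3.2). Digestion, preparation and loss of a Swi/Snf subunit stay open and untested, since each genotype had 1 library.

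The chromosome 10 segment lacked reads in the Snf5-deficient library. The other libraries held reads there, at 0.898 or more of the density of the flanks, so reads can be aligned to the segment. The search demanded reads in the other libraries, so it could not have listed a segment without alignable sequence. This is therefore no separate test. Counting noise alone gave 0 missing segments in 20 simulated libraries under the definition chosen afterwards. The real wild-type library had 5 under that definition and the Brg1-deficient library 54. The simulation thus does not show how often a segment arises without a targeted deletion. A deletion made by Cre at Smarcb1 is a candidate explanation, and a deletion carried by the strain is another. Neither was tested, since no annotation of the build was used, and the place was first looked at because of a recalled position of that gene.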
